A study of Brassica oleracea with 12 samples.

How the data were processed

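RNA was taken from leaf parts of the kale cultivar JC007-2B, and poly(A) RNA was sequenced in paired-end reads on an Illumina HiSeq instrument, per the labels. The 12 libraries stand for whole leaves without veins at S1 and S2 and for the red center (S3_C) and green margin (S3_S) at S3, with 3 libraries in each of 4 groups. The labels do not say whether the 3 libraries of a group came from separate plants, so the p-values measure only the spread between samples, which may be technical in part. The deposited table gives FPKM per gene and library, computed by the authors. The submitters' processing notes name HISAT2 2.0, StringTie 1.3.0 and Bowtie 0.12.2 without their roles, and no genome build, annotation release or filter is given in the sources used here. Of the 45714 entries, 34969 carry identifiers that StringTie gives to merged transcripts, 839 name more than 1 annotated gene, 7287 name none, 10982 have a product description, 7917 (17.3%) an Arabidopsis identifier and 22692 gene ontology terms.

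Absolute depth is unknown because read counts are not given in the sources used here. A depth relative to S1 replicate 1 was inferred from the spacing of values under 0.15 FPKM and lay between 0.669 and 1.0, and no interval that needs counts is given. Between 19.75% and 23.28% of entries were listed at 0 in each library. An entry listed at 0 was not read as absence of the transcript, since abundant chloroplast genes such as Bo7g044900 were also listed at 0 in some libraries, and no fold is printed against a group listed at 0. Among the 27272 tested genes, pairs of libraries within a group had exactly equal values in at most 1.03%, which was checked to exclude copied columns.

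Genes with at least 1 FPKM in at least 3 of the 12 libraries (27272, or 59.7%) were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group means, all 12 libraries, eBayes with a trend, and two-sided moderated tests. P-values were adjusted by the Benjamini-Hochberg method within each of 6 comparisons, and genes were called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low values. The comparisons, the test, the filter, the gene lists, the rule for named genes and the alternatives described as such were fixed before the data were examined. Settings and tests said to be added were chosen later.

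There were 27 gene lists with 304 members, matched by Arabidopsis identifier, product description or exact symbol. In all, 129 genes were matched and 98 tested. The 12 lists with at least 3 tested members were compared with all other tested genes by camera (limma) with its preset correlation of 0.01, and adjusted over the lists within each comparison: early flavonoid (4 tested genes), general phenylpropanoid (3), chlorophyll biosynthesis (12), chlorophyll breakdown (4), light harvesting antenna (20), photosystem subunits (6), Calvin cycle (9), carotenoid biosynthesis (8), cell division (6), leaf patterning (4), circadian clock (4) and vascular markers (4). Camera with an estimated correlation and fry, which tests whether the genes of a list move one way without comparing them with other genes, were run beside it. Members were also counted over all genes and adjusted over the list alone. Lists with fewer tested genes have values and no list test: anthocyanin activators and repressors, chloroplast development regulators, cell expansion, aliphatic and indolic glucosinolate, senescence, cold response, heat shock, jasmonate and epidermal markers. Late anthocyanin biosynthesis had 0 matched genes, and salicylate defense, stomatal lineage and shoot meristem had 0 tested. Gene ontology terms with at least 10 tested members (648) were tested with camera in a step added after the values were seen, and 11 terms were tested again without each library in turn.

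The rule for named genes took the 5 largest changes in each direction among called genes with an informative name, no overlap between groups and a mean of at least 5 FPKM in the higher group, up to 4 called members and the most abundant tested member of each list, and all tested members of the anthocyanin and chloroplast regulator lists. As few genes were called, a rule added after the values were seen also took, with the same conditions, genes from the 6 largest differences in each direction among genes at an unadjusted p under 0.05. The called genes Bo8g082410 and Bo9g120520, which lack an informative name, and the list members Bo6g068550, LHCA4, PSBR, GAPB, PCNA1, CDC2B, AtGRF1, ACD1, NOL, ACD2, PORB, ATEXPA3, ATGSR1, AOS and XCP1 fall outside the rule for their list, and CIP7, ARR12, CRY1, ELP6 and ARF10 lie outside the lists. These were chosen after their values were seen.

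Calls were tested on simulated data with 50 changed genes of each size among 27272. In S2 against S1, 8, 31, 36 and 45 of 50 were recovered at log2 changes of 1, 2, 3 and 4 with 6 false calls, and in S3_S against S3_C 10, 31, 37 and 46 with 12 false calls. Camera called 0 of 20 lists without a change in each of these comparisons and 1 of 20 in S3_C against S2. The noise was drawn independently for each gene, and only genes with a mean log2(FPKM + 1) above 2 were changed. Members of the real lists vary together, with estimated correlations such as 0.879 for the Calvin cycle and 0.722 for early flavonoid genes. No simulated library stood apart from its group. These figures therefore do not carry over to the real lists and libraries. Whether equal replicate numbers pair the samples was checked from the correlation of deviations from group means, which had to exceed 0.1 in each pair. This held for S3_S and S3_C alone. The alternatives were median-of-ratios scaling, quantile normalization, a pseudocount of 0.1, no filter, a minimum of 5 FPKM, eBayes without a trend, a fit to the 6 libraries compared, the replicate number as a block, array quality weights, a minimum change of 2-fold and leaving out each library in turn. A fit without both S1 replicate 1 and S3_S replicate 3, and a block within the 6 libraries of S3_S and S3_C, were added after the values were seen. No library was left out of the reported values.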

Results

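Messenger RNA was measured in 12 leaf libraries of the ornamental kale cultivar JC007-2B (Brassica oleracea var. acephala), whose leaves are red when young and later red in the center with a green margin. The libraries form 4 groups with 3 libraries each. S1 is the whole red leaf without veins, S2 is the whole leaf without veins once the margin is green, S3_C is the red center at the third stage and S3_S is the green margin at that stage. Values are FPKM, and 27272 of 45714 listed genes reached 1 FPKM in at least 3 libraries and were tested. FPKM summed to between 426981 and 470320 per library. Read counts are not given in the sources used here, so the absolute depth is unknown. Relative to S1 replicate 1, the depth inferred from the lowest values lay between 0.669 (S3_S replicate 2) and 1.0. The table gives no gene positions, and no genome build is named in the sources used here.

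The libraries did not sort cleanly by group. Across genes, pairs of libraries from the same group correlated at r = 0.749 to 0.935 (median 0.873) and pairs from different groups at r = 0.645 to 0.952 (median 0.863), with genes not being independent replicates. S1 replicate 1 was closest to S2 replicate 2 (r = 0.941) and had r = 0.749 and 0.761 with the other two S1 libraries, which had r = 0.935 with each other. S3_S replicate 3 was closest to S1 replicate 3 (r = 0.912) and had r = 0.855 and 0.852 with the rest of its group. In the first principal component, with 45.2% of the variance, S1 replicates 2 and 3 and S3_S replicate 3 stood at 130.8, 128.8 and 77.7 and S1 replicate 1 at -35.9.

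**Figure D1:**
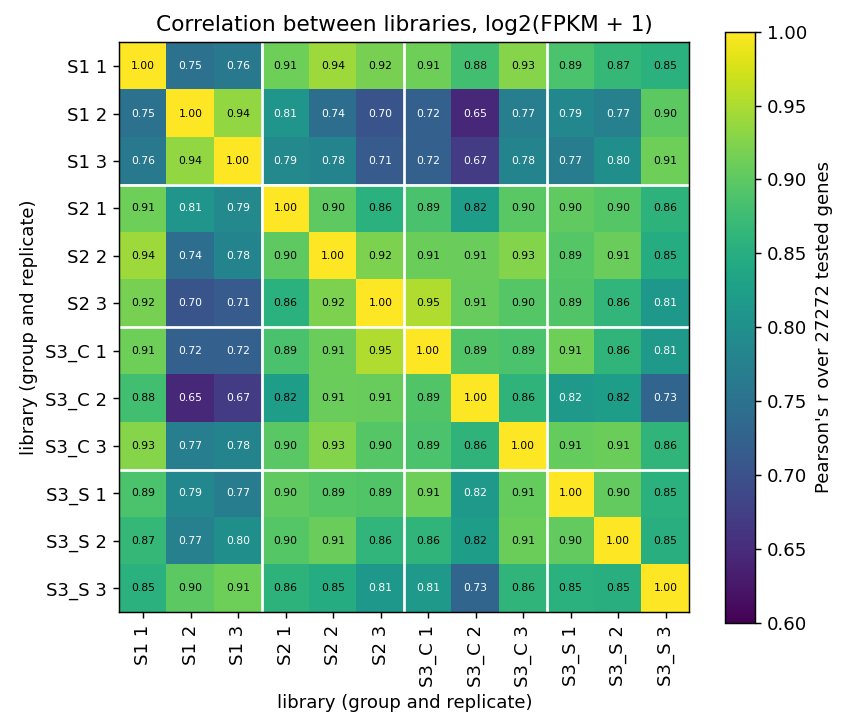
Pearson correlation across tested genes between all pairs of the 12 libraries, on log2(FPKM + 1), with libraries in group order on both axes. S1 replicate 1 lies nearer to S2 replicate 2 (0.941) than to the other S1 libraries (0.749 and 0.761), and S3_S replicate 3 is nearest to S1 replicate 3 (0.912).

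S2 against S1 compares the leaf with a green margin with the earlier red leaf. Early flavonoid genes, which make the precursors of the red anthocyanins, fell as a list: all 4 tested members had lower means in S2, with a median log2 fold change of -2.26 (camera adjusted p = 0.00184, and adjusted p = 0.396 with an estimated correlation between members). TT7, the flavonoid 3'-hydroxylase, averaged 23.4 ± 22.4 FPKM in S1 and 0.543 ± 0.423 in S2 (SD, n = 3). Genes of the photosynthetic machinery rose as lists: light harvesting antenna (median 1.16, 16 of 20 members above 0, adjusted p = 5.12e-05), photosystem subunits (1.14, 6 of 6, 0.004300) and Calvin cycle (1.21, 9 of 9, 0.00184), each at an adjusted p of 0.396 with an estimated correlation. The cell division list fell (median -1.73, 4 of 6 members below 0, adjusted p = 0.0407) and the circadian clock list rose (0.503, 4 of 4 above 0, 0.0138). With an estimated correlation between list members, none of these 6 lists passed (camera adjusted p = 0.396 for each), and fry gave 0 lists (smallest adjusted p = 0.185).

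Gene by gene, limma called 0 genes higher and 2 lower in S2 than in S1. At an unadjusted p under 0.05 there were 3297 genes (1009 higher, 2288 lower), where chance gives 1364. Both called genes were listed at 0 in all 9 libraries outside S1: Bo8g082410, annotated to cell redox homeostasis, had 8.13, 18.7 and 22.1 FPKM in the 3 S1 libraries, and Bo9g120520, which has no description, had 29.2, 10.1 and 79.2. The adjusted p was 0.00182 for the first and 0.0243 for the second. The groups did not overlap in 4.71% of genes with the higher values in S2 and in 6.70% with the lower, where chance gives 10% over both directions. The count rests on S1 replicate 1: without it, 1278 genes were higher and 2984 lower in S2, and without both it and S3_S replicate 3, a setting added after the values were seen, 1536 and 3634. It was 4 lower without S2 replicate 1 or S3_S replicate 3, 1 higher and 1 lower without S2 replicate 2, and 1 lower without S2 replicate 3, any S3_C library, or S3_S replicate 1 or 2.

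In the early flavonoid list, 0 of 4 members passed over all genes and 4 passed when adjusted over the list alone. TT7 had a log2 fold change of -3.34 (SE 0.95) and the chalcone isomerase homolog Bo6g068550 had -2.77 (SE 0.87), from 17.7 ± 11.7 FPKM in S1 to 1.42 ± 0.97996 in S2. Within S1 the list was uneven, with TT7 at 2.37, 47.01 and 20.9 FPKM in replicates 1, 2 and 3. TT8, the bHLH activator of anthocyanin genes and the single tested member of its list, averaged 16.2 ± 11.4 FPKM in S1 and 3.05 ± 4.08 in S2 and did not pass (limma adjusted p = 0.403). The COP1 homolog Bo4g045420, an anthocyanin repressor, had 9.69 ± 1.94 and 11.9 ± 1.43 FPKM. In the general phenylpropanoid list, which did not pass (median -1.24, camera adjusted p = 0.232), 0 of 3 members passed over all genes and 2 adjusted over the list alone, with 4CL1 at 6.79 ± 4.89 FPKM in S1 and 1.89 ± 0.708 in S2. No member of the late anthocyanin list was matched in the table, so the last steps of pigment synthesis were not analysed here. Without S1 replicate 1, all 4 early flavonoid genes and TT8 were called lower in S2.

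In the antenna list, 0 of 20 members passed either over all genes or adjusted over the list alone. Its most abundant member, the photosystem I antenna gene Bo4g101180, averaged 966 ± 1196 FPKM in S1 and 1885 ± 563 in S2, and LHCA4 averaged 846 ± 1040.3 and 1794 ± 812. S1 replicate 1 had S2-like levels of these genes: LHCA4 was at 2047, 262 and 229 FPKM in the 3 S1 libraries. The photosystem and Calvin cycle lists also had 0 members called over all genes and 0 adjusted over the list alone. Among their members, PSBQ of photosystem II averaged 775 ± 785 and 1396 ± 267 FPKM, PSBR 184 ± 236 and 304 ± 114, the Rubisco small subunit entry Bo4g137150;Bo4g137140;Bo4g137200 485 ± 429.8 and 1067 ± 543, and the chloroplast dehydrogenase GAPB 139 ± 183 and 399 ± 308. Without S1 replicate 1, 10 of 20 antenna genes, 4 of 6 photosystem genes and 2 of 9 Calvin cycle genes were called higher in S2, and the list medians were 1.82, 1.802 and 2.004. The Calvin cycle median was 0.79 without S1 replicate 2.

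Of the 6 tested cell division genes, 0 passed over all genes and 4 adjusted over the list alone. PCNA1, the sliding clamp of DNA replication, averaged 7.14 ± 6.23 FPKM in S1 and 0.2898 ± 0.144 in S2, and the mitotic kinase CDC2B 5.92 ± 5.48 and 0.183 ± 0.0322. The other two members of the list, CYC1 (18.9 ± 4.18 and 20.4 ± 8.81) and AtGRF1 (3.54 ± 0.326 and 4.01 ± 0.806), did not have lower means in S2. GI, the most abundant clock gene tested, averaged 22.4 ± 4.84 and 28.5 ± 1.69 FPKM, and 0 of the 4 clock genes passed over all genes or adjusted over the list alone. The cell division call was lost without S1 replicate 3, S2 replicate 1, S2 replicate 2, S3_C replicate 2 or S3_C replicate 3 (adjusted p from 0.0504 to 0.154 in those fits, from 0.00871 over all fits without 1 library), and with a pseudocount of 0.1 (median -2.84, adjusted p = 0.0578). The clock call was lost without S1 replicate 3 (median 0.31, adjusted p = 0.05195) or S2 replicate 1 (0.25, 0.0921), with a median of 0.76 without S1 replicate 1, and the photosystem and Calvin cycle calls without S2 replicate 3 (0.0647 for each).

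The remaining 5 lists did not pass in S2 against S1. Chlorophyll biosynthesis had a median of 0.097 (adjusted p = 0.384), chlorophyll breakdown 0.43 (0.0809), carotenoid biosynthesis 0.25 (0.284), leaf patterning -0.11 (0.666) and vascular markers -0.54 (0.162). The chlorophyll breakdown, carotenoid and vascular medians were 0.88, 0.51 and -0.83 without S1 replicate 1. Chlorophyll breakdown passed without S1 replicate 1 (0.0229) or S2 replicate 1 (0.0135, median 0.66), and chlorophyll and carotenoid biosynthesis without S2 replicate 1 (0.0357 for each, medians 0.27 and 0.47). The genes with the largest differences among those at an unadjusted p under 0.05, none of which passed (limma adjusted p = 0.403 for each), included BPS1 (0.945 ± 0.439 FPKM in S1, 49.1 ± 45.6 in S2), the lycopene cyclase Bo5g137670 (4.02 ± 4.17, 35.2 ± 22.5), the chloroplast ATP synthase subunit Bo1g010620 (65.1 ± 42.3, 518 ± 272), the oleosin Bo8g050570 (11.9 ± 17.1, 46.5 ± 9.04), the PLATZ transcription factor Bo6g120700, 1 of 2 tested entries of that name (19.8 ± 22.2, 117 ± 58.2) and the TPR-like protein Bo1g010520 (6.49 ± 3.07, 42.98 ± 7.93). With lower means in S2 were the malate transporter Bo7g014450 (45.7 ± 34.3, 3.06 ± 3.74), the heavy metal transport protein Bo3g024150 (46.8 ± 37.2, 1.77 ± 1.16), the peroxidase Bo6g099630 (40.03 ± 63.4, 0.147 ± 0.128), the histone H2A entry Bo3g017690;Bo3g017700 (28.5 ± 24.96, 0.819 ± 0.263) and the lipid transfer protein LTP4 (25.6 ± 10.9, 3.52 ± 2.87).

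**Figure D2:**
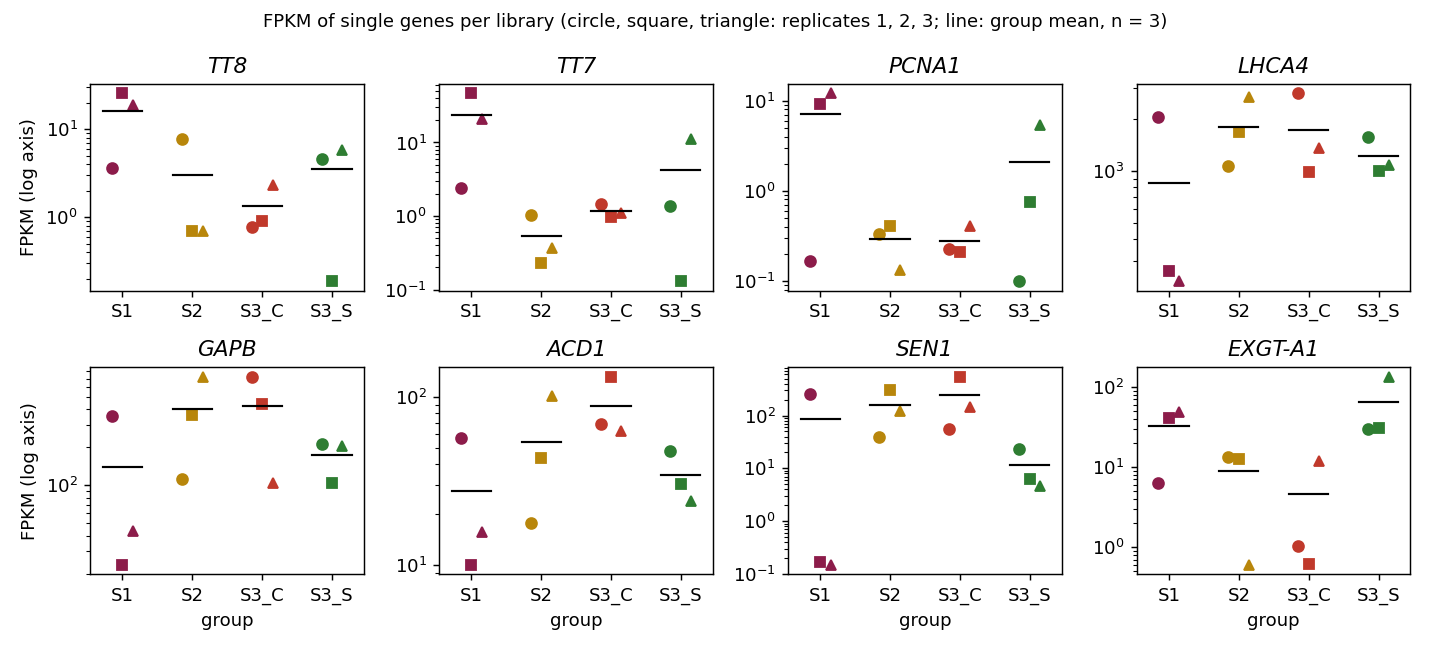
FPKM on a log axis of 8 genes in each library, with points for libraries and lines for the mean of each group of 3. S1 replicate 1 lies outside the range of S1 replicates 2 and 3 in each of the 8, for example with LHCA4 at 2047, 262 and 229 FPKM.

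S3_S against S3_C compares the green margin with the red center of the same leaf stage. Chlorophyll breakdown genes fell as a list in the margin: all 4 tested members had lower means there, with a median log2 fold change of -1.01 beside a median of 0.18 for all genes (camera adjusted p = 0.00817, and adjusted p = 0.876 with an estimated correlation). The size rests in part on S3_C replicate 2, without which the median was -0.57 (adjusted p = 0.0319). ACD1, the pheophorbide a oxygenase that opens the chlorophyll ring, averaged 34.1 ± 12.3 FPKM in the margin and 87.997 ± 38.3 in the center (SD, n = 3). The chlorophyll b reductase homolog NOL averaged 9.201 ± 1.52 and 17.35 ± 6.88, the red chlorophyll catabolite reductase ACD2 1.51 ± 0.693 and 6.12 ± 5.62, and the entry Bo5g004750;Bo5g004760, a hydroxymethyl chlorophyll reductase homolog, 52.02 ± 8.87 and 66.4 ± 7.68. No list of red pigment genes passed between the red center and the green margin: the early flavonoid list had a median of 0.42 (adjusted p = 0.866) with all libraries and -0.24 (0.505) without S3_S replicate 3, so its direction rests on that library. The chlorophyll breakdown call was also lost with median-of-ratios scaling (adjusted p = 0.0508, median -1.21), and 0 of the 4 members passed over all genes or adjusted over the list alone.

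Limma called 0 genes in either direction between margin and center (smallest adjusted p = 0.0815). At an unadjusted p under 0.05 there were 2825 (2036 higher in the margin, 789 lower), where chance gives 1364. The groups did not overlap in 11.9% of genes with the higher values in the margin and 4.85% with the lower, where chance gives 10% over both directions. Median-of-ratios scaling moved the median of all genes from 0.18 to 0.01 and the unadjusted counts to 1283 higher and 1450 lower. The same scaling moved that median from -0.09 to 0.02 in S2 against S1 and from -0.18 to 0.01 in S3_C against S1. Equal replicate numbers met the criterion for pairing in this comparison alone (deviations correlated at 0.268, 0.195 and 0.158). Over all groups, 11 of 36 pairs with other numbers also exceeded 0.1 (highest 0.373). The labels do not say whether equal numbers share leaves, so pairing is not established. With the replicate number as a block limma called 0 genes and camera 1 list. A block fitted to the 6 libraries of these groups, added after the values were seen, gave 0 genes and 4 lists, all lower in the margin: chlorophyll breakdown (adjusted p = 0.00393), antenna (0.0493), photosystem subunits (0.0381) and Calvin cycle (0.0381). This block was run only with the preset correlation. Without the block, camera with an estimated correlation gave an adjusted p of 0.876 for each of these 4 lists. Without S3_C replicate 1, 5 genes were called lower.

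The photosynthesis lists had medians below 0 in the margin and did not pass: antenna -0.22 (camera adjusted p = 0.256, 13 of 20 members below 0), photosystem subunits -0.47 (0.194, 5 of 6) and Calvin cycle -0.57 (0.0847, 8 of 9). Bo4g101180 averaged 1190.4 ± 383 FPKM in the margin and 1828 ± 1201 in the center, PSBQ 913 ± 288 and 1274 ± 558, GAPB 174 ± 61.004 and 422 ± 307, and the Rubisco entry Bo4g137150;Bo4g137140;Bo4g137200 644 ± 435 and 1023 ± 909.6. The Calvin cycle list passed without S1 replicate 1 (0.0396), S3_C replicate 3 (0.00105, median -1.22) or S3_S replicate 3 (0.00798). Photosystem subunits passed without S1 replicate 1 (0.0396) and the antenna without S3_C replicate 2 (0.0319, median -0.49). These fits gave counts of 2 or 3 called lists. Leaving out S1 replicate 1 left both medians unchanged, since it enters this comparison only through the shared spread. Chlorophyll biosynthesis had a median of 0.11 (adjusted p = 0.866), with PORB, a light-dependent step of chlorophyll synthesis, at 70.01 ± 37.2 FPKM in the margin and 35.1 ± 20.4 in the center. Carotenoid biosynthesis had -0.24 (0.194), general phenylpropanoid 0.795 (0.848), cell division 0.43 (0.866), leaf patterning 0.23 (0.848), clock 0.14 (0.866) and vascular markers 0.65 (0.194). Without S3_S replicate 3 the general phenylpropanoid, cell division and vascular medians were 0.08, 0.00 and 0.31, the clock median 0.26 and the Calvin cycle median -0.96. The antenna and chlorophyll biosynthesis medians were then -0.12 and 0.07. Each of these lists had 0 members called over all genes and 0 adjusted over the list alone.

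Of the largest differences at an unadjusted p under 0.05, none passed (limma adjusted p = 0.476 for each). The wall-loosening enzyme EXGT-A1 averaged 65.03 ± 59.9 FPKM in the margin and 4.56 ± 6.46 in the center (log2 fold change 3.87, SE 1.103). The pectin lyase-like gene Bo5g141950 averaged 90.98 ± 65.4 and 13.6 ± 19.8, the peroxidase PRXR1 89.6 ± 119.98 and 3.11 ± 2.696, the receptor kinase TMK1 20.6 ± 0.596 and 2.195 ± 3.104, and the cysteine proteinase inhibitor Bo8g044690 58.6 ± 88.3 and 1.71 ± 2.97. The histone H2A gene Bo9g140890 had 3.76, 5.26 and 15.9 FPKM in the margin and was listed at 0 in the center. In the other direction, the methyltransferases Bo5g050740 and Bo5g050750 were listed at 0 in the margin. They had 26.7, 22.1 and 36.4 and 26.9, 21.9 and 34.2 FPKM in the center. Whether these nearly equal values are separate signals was not tested, and listing at 0 is not read as absence. The beta-galactosidase Bo2g032970 averaged 6.97 ± 2.49 FPKM in the margin and 295 ± 325 in the center, the dark-inducible senescence gene SEN1 11.6 ± 10.5 and 248 ± 259, the pyruvate, phosphate dikinase entry Bo1g056690;Bo1g056680 1.17 ± 0.731 and 35.5 ± 26.6, and the alpha-galactosidase Bo2g009060 2.72 ± 2.72 and 39.4 ± 22.4. SEN1 was uneven in the center, at 55.9, 543 and 145 FPKM in its 3 libraries. TT8 averaged 3.53 ± 2.96 FPKM in the margin and 1.34 ± 0.876 in the center, and TT7 4.26 ± 6.12 and 1.17 ± 0.257, with S3_S replicate 3 at 11.3.

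**Figure D3:**
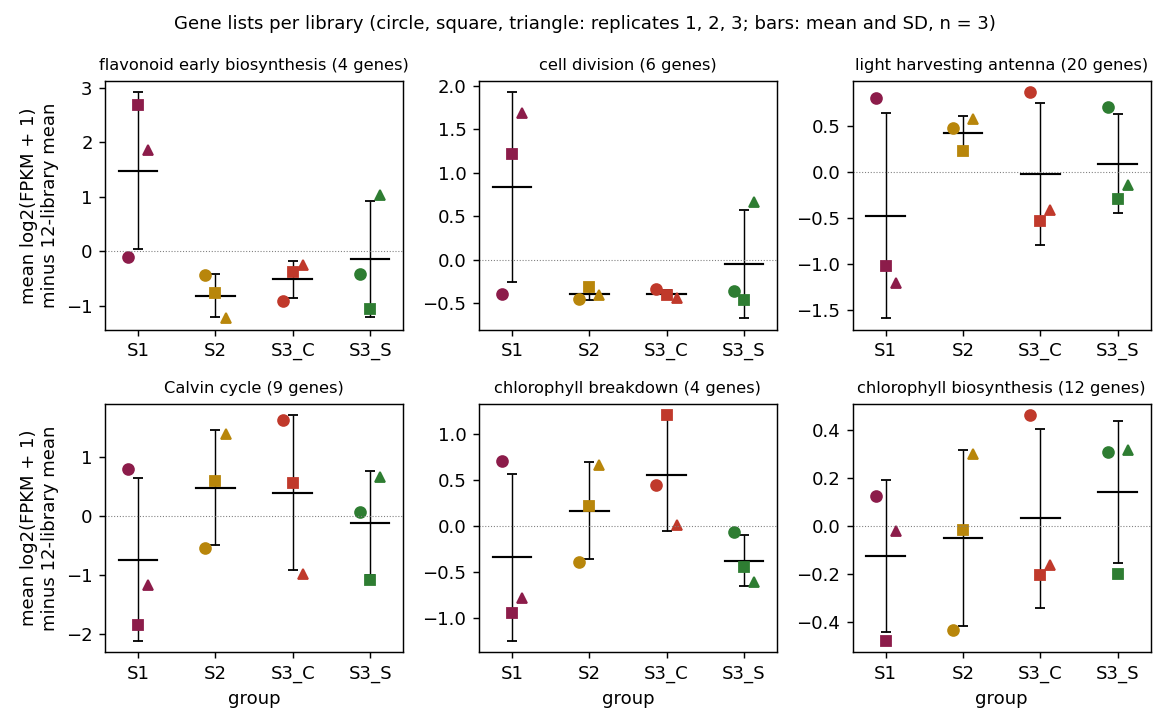
Mean deviation of 6 gene lists in each library, in log2(FPKM + 1) from the mean of all 12 libraries, with points for libraries and bars for the mean and SD of each group of 3. The cell division list stands at 1.21 and 1.69 in S1 replicates 2 and 3, 0.665 in S3_S replicate 3 and -0.393 in S1 replicate 1.

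S3_C against S2 compares the red center at the third stage with the whole leaf before it. No list passed, and the largest medians were those of the clock (-0.25, camera adjusted p = 0.293, 4 of 4 members below 0), general phenylpropanoid (0.31, 0.439), early flavonoid (0.302, 0.439) and chlorophyll breakdown lists (0.24, 0.293, 4 of 4 above 0). These medians rest on single libraries: those of the clock and chlorophyll breakdown were -0.06 and -0.04 without S3_C replicate 2. The clock and early flavonoid medians were -0.07 and 0.49 without S2 replicate 1. The general phenylpropanoid median was -0.14 without S2 replicate 2. In the antenna list, 17 of 20 members had the lower mean in the center (median -0.18, adjusted p = 0.439, with a median of 0.08 without S3_C replicate 2). Limma called 0 genes in either direction (smallest adjusted p = 1), beside 335 at an unadjusted p under 0.05 (175 higher, 160 lower, and 259 and 127 with median-of-ratios scaling). These 335 genes are fewer than the 1364 that chance gives. The shared spread includes the uneven S1 libraries, which are not compared here, so these p-values may be too large. The groups did not overlap in 1.503% of genes with the higher values in the center and 2.55% with the lower, where chance gives 10% over both directions.

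Among the largest differences of S3_C against S2, none of which passed (adjusted p = 1 for each), the homeodomain-like gene Bo7g031620 had 17.398, 14.7 and 16.6 FPKM in the center and was listed at 0 in S2. The glucanase BG3 averaged 16.5 ± 13.6 FPKM in the center and 2.26 ± 0.738 in S2, the O-methyltransferase Bo8g070660 11.8 ± 9.59 and 1.97 ± 1.36, and the MLO-like gene Bo4g188000 5.3997 ± 5.63 and 0.283 ± 0.368. The peroxidase Bo1g003570 averaged 11.3 ± 12.4 and 1.53 ± 0.905, and the lectin kinase Bo3g081630 12.1 ± 7.09 and 2.89 ± 0.906. The spindle checkpoint homolog Bo9g177080 averaged 1.57 ± 0.372 in the center and 6.397 ± 0.989 in S2, and the ubiquitin ligase KEG 5.75 ± 2.39 and 10.1 ± 1.96. TT8 averaged 1.34 ± 0.876 and 3.05 ± 4.08 FPKM. The higher S2 mean rests on S2 replicate 1 (7.77 FPKM). S2 replicates 2 and 3, at 0.696 and 0.694, lay below every center library (0.774, 0.9002 and 2.35). Without S3_C replicate 1, 4 genes were called higher and the antenna list lower (adjusted p = 0.000288, median -0.66). Chlorophyll breakdown and biosynthesis passed without S2 replicate 3 (0.0181 and 0.0125, medians 0.34 and 0.26). Both, with the Calvin cycle, passed without S3_C replicate 3 (0.0133, 0.0217 and 0.00782, medians 0.67, 0.16 and 0.72, where all libraries gave 0.24, 0.06 and 0.05). In the gene counts, 1 was called higher without S1 replicate 2 or S2 replicate 1.

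S3_S against S2 compares the green margin at the third stage with the earlier whole leaf. Chlorophyll breakdown (median -0.499, 4 of 4 members below 0), light harvesting antenna (-0.41, 16 of 20) and Calvin cycle genes (-0.58, 9 of 9) fell as lists in the margin (camera adjusted p = 0.0459 for each, and adjusted p = 0.5605 for each with an estimated correlation). These sizes moved with single libraries: without S2 replicate 3 the medians were -0.24, -0.23 and -0.11, and without S3_S replicate 2 the antenna and Calvin cycle medians were -0.24 and -0.26. They were larger for chlorophyll breakdown and Calvin cycle without S2 replicate 1 (-0.89 and -1.202), for the antenna without S3_S replicate 1 (-0.67) and for the Calvin cycle without S3_S replicate 3 (-1.04). GAPB averaged 174 ± 61.004 FPKM in the margin and 399 ± 308 in S2, and Bo4g101180 1190.4 ± 383 and 1885 ± 563. The 3 calls were also lost with median-of-ratios scaling (camera adjusted p = 0.101 for each), although the medians were somewhat larger, at -0.61, -0.53 and -0.70. In all 3 lists 0 members passed over all genes or adjusted over the list alone. General phenylpropanoid genes did not pass as a list (median 0.696, adjusted p = 0.182, with a median of -0.02 without S3_S replicate 3), and 1 member passed adjusted over the list alone, with 4CL1 at 5.73 ± 1.54 FPKM in the margin and 1.89 ± 0.708 in S2.

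Limma called 0 genes in either direction in S3_S against S2 (smallest adjusted p = 0.893), beside 896 at an unadjusted p under 0.05 (556 higher and 340 lower, but 477 and 453 with median-of-ratios scaling and 504 and 525 with quantile normalization). These 896 genes are fewer than the 1364 that chance gives. The spread was estimated over all 12 libraries, including the uneven S1 group, so the p-values of this comparison may be too large. The groups did not overlap in 11.2% of genes with the higher values in the margin and 4.63% with the lower, where chance gives 10% over both directions. Among the largest differences, none of which passed (adjusted p = 0.893 for each), the SWEET sugar transporter Bo5g034370 averaged 37.2 ± 16.8 FPKM in the margin and 8.42 ± 6.52 in S2, the auxin-responsive gene Bo3g066910 16.97 ± 19.9 and 1.83 ± 1.21, EXGT-A1 65.03 ± 59.9 and 8.81 ± 7.12, and the purine permease PUP5 12.5 ± 8.96 and 1.82 ± 0.725. With lower means in the margin were the ATP synthase subunit Bo1g010620 (12.3 ± 1.91 and 518 ± 272), BPS1 (2.29 ± 1.47 and 49.1 ± 45.6), the receptor-associated protein Bo8g108590 (3.46 ± 3.92 and 26.3 ± 8.59) and the UDP-glucose epimerase Bo1g037320 (7.76 ± 5.696 and 30.8 ± 10.5). The number of called lists was 0 without S2 replicate 3, S3_C replicate 2 or S3_S replicate 2, 1 without S3_S replicate 3, 5 without S2 replicate 1 or S3_S replicate 1, and 6 without S2 replicate 2. Photosystem subunits passed as well without S1 replicate 1 (0.00784) or S1 replicate 3 (0.0325), and chlorophyll breakdown was lost without S3_C replicate 1 (0.0579). Without S2 replicate 1, 2 genes were called higher, and 1 without S1 replicate 2. With the replicate number as a block, chlorophyll breakdown and Calvin cycle were lost (0.0573 for each).

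S3_C against S1 compares the red center with the red leaf of the first stage. Early flavonoid genes fell as a list, with both samples described as red: the median was -1.78 beside a median of -0.18 for all genes, with 4 of 4 members below 0 (camera adjusted p = 0.0227, and adjusted p = 0.478 with an estimated correlation). TT8 averaged 1.34 ± 0.876 FPKM in the center and 16.2 ± 11.4 in S1, and TT7 1.17 ± 0.257 and 23.4 ± 22.4. Chlorophyll breakdown (median 0.58, 4 of 4 above 0, adjusted p = 0.0177), antenna (0.91, 15 of 20, 0.00434), photosystem (1.02, 5 of 6, 0.0177) and Calvin cycle genes (1.25, 8 of 9, 0.00434) rose as lists. With an estimated correlation none of the 5 lists passed (adjusted p = 0.478 for each). The medians of the 4 rising lists, in that order, were 1.12, 1.59, 1.71 and 1.97 without S1 replicate 1. They were lower for chlorophyll breakdown, photosystem and Calvin cycle without S1 replicate 2 (0.37, 0.64 and 0.83), for antenna and photosystem without S1 replicate 3 (0.602 and 0.63) and for antenna and Calvin cycle without S3_C replicate 1 (0.48 and 0.72), and higher for chlorophyll breakdown and Calvin cycle without S3_C replicate 3 (0.98 and 1.89). Of the early flavonoid genes 0 passed over all genes and 3 adjusted over the list alone, and of the cell division genes, which did not pass as a list (median -1.68, adjusted p = 0.0921), 0 and 4. The other 4 called lists had 0 members called either way.

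Limma called 0 genes higher and 2 lower in S3_C than in S1, Bo8g082410 and Bo9g120520 again. At an unadjusted p under 0.05 there were 5970 (1668 higher, 4302 lower), where chance gives 1364. Median-of-ratios scaling moved the higher and lower counts to 2737 and 2939. The groups did not overlap in 5.28% of genes with the higher values in the center and 10.1% with the lower, where chance gives 10% over both directions. Among the largest differences, the glutamine synthetase ATGSR1, a nitrogen-recycling enzyme of senescing leaves, averaged 48.7 ± 17.63 FPKM in the center and 6.36 ± 8.11 in S1 (adjusted p = 0.213). The carbonic anhydrase ATBCA3 averaged 95.9 ± 94.7 and 1.68 ± 2.82, the superoxide dismutase Bo7g109980 37.9 ± 22.2 and 0.0833 ± 0.108, the cystatin Bo3g003170 44.2 ± 42.7 and 1.63 ± 1.58, and the aquaporin PIP2B 127 ± 168 and 8.07 ± 7.86. With lower means in the center were PRXR1 (3.11 ± 2.696 and 339 ± 277), LTP4 (0.478 ± 0.694 and 25.6 ± 10.9), the cinnamyl alcohol dehydrogenase ATCAD9 (3.39 ± 1.72 and 110.2 ± 86.8) and the fatty acyl-CoA reductases Bo3g016880 (0.518 ± 0.462 and 88.3 ± 103) and Bo1g007830 (12.3 ± 10.5 and 131 ± 73.4). CER1, a wax synthesis gene of the epidermis, averaged 28.2 ± 21.4 and 172 ± 59.3.

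Without S1 replicate 1, 1747 genes were called higher and 4540 lower in S3_C than in S1, and without both it and S3_S replicate 3, 1932 and 4920. Without S1 replicate 1 alone, TT8 was called lower (log2 fold change -3.37, SE 0.85, limma adjusted p = 0.0208), as were TT7 (-3.91, adjusted p = 0.0108), CER1 (-3.25, 0.0467) and EXGT-A1 (-3.72, 0.0399), and SEN1 (7.15, 0.00527), ATGSR1 (4.16, 0.0102) and ACD1 (2.63, 0.0169) were called higher. The cell division list passed in that fit (0.0127, median -2.504). The number of called lists was 0 without S3_C replicate 1 and 1 without S1 replicate 2. The photosystem call was lost without S1 replicate 3 (0.0909), the chlorophyll breakdown call without S3_C replicate 2 (0.06101) and the early flavonoid call without S3_C replicate 3 (0.0797). Chlorophyll biosynthesis passed without S1 replicate 3 (0.04598), S3_C replicate 2 (0.0459) or S3_C replicate 3 (0.04902), with medians of 0.17, 0.19 and 0.16 against 0.08 with all libraries. The clock and cell division lists passed without S3_C replicate 2 (0.0459 for each, with a clock median of 0.41 against 0.22 with all libraries). Without S3_C replicate 1, 5 genes were called higher, and without S2 replicate 2, 1 was. The count of lower genes was 4 without S3_S replicate 3 and 1 without S2 replicate 3, S3_C replicate 2 or 3, or S3_S replicate 1 or 2.

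S3_S against S1 compares the green margin with the red leaf of the first stage. Early flavonoid (median -1.81, 4 of 4 members below 0, camera adjusted p = 0.00745) and cell division genes (-1.099, 5 of 6 below 0, 0.00879) fell as lists, and antenna genes rose (0.73, 16 of 20 above 0, 0.00745). With an estimated correlation the adjusted p were 0.675 for both falling lists and 0.832 for the antenna. Without S1 replicate 1 the antenna and cell division medians were 1.38 and -1.96, without S1 replicate 2 the antenna and early flavonoid medians 0.36 and -1.09, and without S1 replicate 3 the antenna and cell division medians 0.44 and -0.53. Without both S1 replicate 1 and S3_S replicate 3, the early flavonoid, cell division and antenna medians were -3.16, -2.39 and 1.56. All 3 lists had 0 members called over all genes and 0 adjusted over the list alone. COR78, a cold and drought response gene, averaged 692 ± 192 FPKM in the margin and 78.2 ± 31.2 in S1 (log2 fold change 3.17, SE 0.69) and did not pass (limma adjusted p = 0.824). The calcium pump Bo2g032750 averaged 94.8 ± 37.1 and 14.4 ± 2.89 FPKM, the SWEET transporter Bo5g034370 37.2 ± 16.8 and 6.66 ± 5.26, and the proline-rich gene Bo7g083920 53.8 ± 42.3 and 8.04 ± 5.53. With lower means in the margin were the chitinase Bo9g055720 (0.789 ± 0.8403 and 11.4 ± 6.49), the calreticulin Bo8g112470 (20.1 ± 18.8 and 103 ± 44.9) and the ion channel ATCNGC3 (6.66 ± 5.86 and 30.3 ± 6.21).

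In S3_S against S1, limma called 0 genes higher and 2 lower, Bo8g082410 and Bo9g120520. At an unadjusted p under 0.05 there were 1552 (790 higher, 762 lower), where chance gives 1364. The groups did not overlap in 5.74% of genes with the higher values in the margin and 3.81% with the lower, where chance gives 10% over both directions. The same 2 genes were called in all 3 comparisons against S1, which share the S1 libraries. In 20 simulated sets of unchanged groups, with noise drawn independently for each gene, the highest number of genes called in all 3 was 0. The simulated noise did not include listing at 0 in some libraries alone, so it cannot decide whether these 2 calls arose that way. Without S1 replicate 1, 99 genes were called higher and 282 lower, and without both it and S3_S replicate 3, 914 and 2165. The photosystem and Calvin cycle lists passed without S1 replicate 1 (0.000522 and 0.00191, medians 1.24 and 1.296 against 0.62 and 0.54 with all libraries). The number of called lists was 0 without S1 replicate 2 and 5 without S3_S replicate 2. The antenna call was lost without S1 replicate 3 (0.257) or S3_S replicate 1 (0.136) and the cell division call without S1 replicate 3 (0.0864), where chlorophyll biosynthesis passed (0.0443). The count of lower genes was 4 without S3_C replicate 3 and 1 without S2 replicate 3, S3_C replicate 1 or 2, or S3_S replicate 1 or 2, and 1 gene was called higher without S2 replicate 2.

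**Figure D4:**
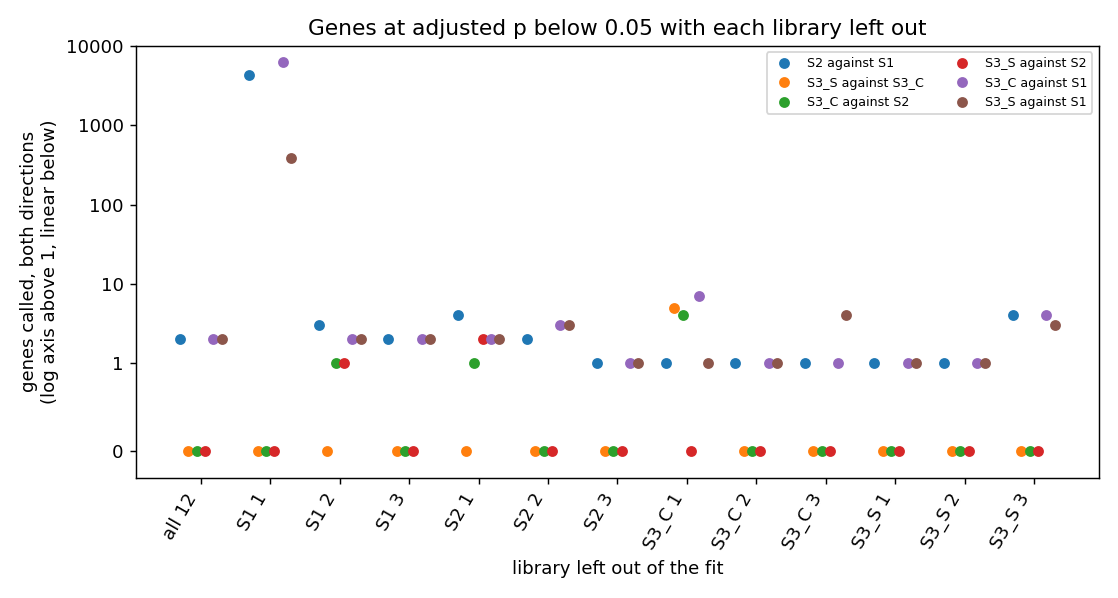
Number of genes called by limma in both directions together in each comparison, with all 12 libraries and after leaving out each library in turn, on a symmetric log axis. Leaving out S1 replicate 1 raised the counts to 1278 higher and 2984 lower in S2 against S1, from 0 and 2 with all libraries.

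Several lists held too few tested genes for a list test, and their members are given as values in the order S1, S2, S3_C and S3_S. None of these genes passed in any comparison with all libraries. Leaving out S1 replicate 1 changed this for several: CYP83A1 was called lower in S2 (log2 fold change -3.38, limma adjusted p = 0.0055), S3_C (-2.93, 0.00643) and S3_S (-2.81, 0.0342) than in S1. ATEXPA3 was called lower in S2 (-3.96, 0.00926) and S3_C (-4.62, 0.00586), and SEN1 higher in S2 (6.65, 0.00654). These stand beside the calls of SEN1, ATGSR1, EXGT-A1 and CER1 in S3_C given above. SIGF, a chloroplast sigma factor and the single tested regulator of chloroplast development, averaged 17.2 ± 3.14, 15.5 ± 4.88, 16.9 ± 4.17 and 16.8 ± 4.24 FPKM. The COP1 homolog Bo4g045420 had 11.3 ± 1.103 in the center and 11.9 ± 1.73 in the margin. Of the cell expansion genes beside EXGT-A1, ATEXPA3 averaged 36.2 ± 30.5, 3.42 ± 3.48, 1.55 ± 1.76 and 14.9 ± 7.27. The glucosinolate genes were the single tested CYP83A1 entry of the aliphatic branch (11.1 ± 11.8, 0.577 ± 0.293, 1.22 ± 0.747 and 1.49 ± 1.18) and CYP83B1 of the indolic branch (10.4 ± 10.99, 2.08 ± 1.38, 2.38 ± 1.69 and 1.301 ± 0.402). Of the senescence genes, SEN1 averaged 85.7 ± 148, 157 ± 137, 248 ± 259 and 11.6 ± 10.5, and ATGSR1 had 19.7 ± 17.5 in S2 and 14.8 ± 16.3 in the margin. COR78 of the cold list had 319 ± 221 in S2 and 283 ± 191 in the center, and HSP81-1 of the heat shock list 1.15 ± 0.818, 2.096 ± 1.93, 0.753 ± 0.806 and 3.15 ± 0.8097. Of the jasmonate genes, OPR3 averaged 23.7 ± 19.2, 20.1 ± 3.09, 12.6 ± 3.34 and 27.6 ± 12.5, and AOS 1.804 ± 1.85, 3.54 ± 3.92, 3.201 ± 2.92 and 2.92 ± 1.96. The epidermal marker CER1 had 65.2 ± 54.99 in S2 and 101 ± 107 in the margin. The salicylate defense, stomatal and shoot meristem lists had 0 tested members. The vascular markers, meant as a check on the removal of veins, passed in no comparison (smallest camera adjusted p = 0.0585, S3_S against S2), with the xylem peptidase XCP1 at 3.001 ± 2.61, 0.5504 ± 0.299, 0.403 ± 0.0476 and 2.82 ± 3.69 FPKM. Tests between groups cannot settle vein removal here, because the libraries with high values cross the groups. The mean deviation of the list was 0.671 and 0.586 in S1 replicates 2 and 3 and 0.992 in S3_S replicate 3. The next highest was S3_S replicate 2 at 0.107. The vascular list did pass in S3_S against S2 without S2 replicate 2 (0.0306) or S3_S replicate 1 (0.0228), and with a pseudocount of 0.1 (0.03903, median 1.31 against 0.66). In lists that were tested, the most abundant members not given above were the chlorophyll synthase ATG4 (48.8 ± 13.9, 63.4 ± 20.3, 66.95 ± 31.8 and 45.4 ± 11.3), the higher of 2 tested entries of the violaxanthin de-epoxidase NPQ1 in the carotenoid list (14.7 ± 5.85, 23.5 ± 12.6, 27.1 ± 8.44 and 16.7 ± 6.45, with the other at 6.06 ± 6.01, 0.491 ± 0.178, 0.206 ± 0.0403 and 1.01 ± 1.45, and called lower in all 3 comparisons against S1 without S1 replicate 1, with limma adjusted p of 0.00959, 0.00621 and 0.0425), the leaf patterning factor TCP10 (14.02 ± 0.0787, 16.5 ± 5.12, 14.8 ± 2.76 and 14.7 ± 3.37) and the vascular marker Bo6g106260, 1 of 2 tested entries of that name (3.32 ± 0.1001, 2.91 ± 1.895, 1.99 ± 1.42 and 3.37 ± 0.586).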

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

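The tests of explanations in this part were chosen only after the result was seen, while the settings they draw on, apart from the block within 6 libraries and the fit without both S1 replicate 1 and S3_S replicate 3, were among the alternatives fixed earlier.

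Chlorophyll breakdown genes differed between the parts of the third-stage leaf: relative to S2, their median was -0.499 in the green margin (4 of 4 members below 0, with -0.24 without S2 replicate 3) and 0.24 in the red center (4 of 4 above 0, with -0.04 without S3_C replicate 2 and 0.67 without S3_C replicate 3), and the test of the difference itself gave a camera adjusted p of 0.00817, and an adjusted p of 0.876 with an estimated correlation. ACD1 averaged 34.1 ± 12.3 FPKM in the margin and 87.997 ± 38.3 in the center (SD, n = 3). Without S3_C replicate 2 the median was still -0.57 (camera adjusted p = 0.0319). This argues against that library alone setting the direction, but not against its part in the size. Over the 12 fits without 1 library the camera adjusted p lay between 0.00261 and 0.0428. These p-values use the preset correlation of 0.01, while the estimate for this list was 0.729. They therefore cannot show that the call is free of single libraries. Members that vary together between libraries could produce the call, since the call was lost with an estimated correlation, and a difference between center and margin in chlorophyll turnover stays open as an untested biological explanation. Scaling between libraries is not decided, because median-of-ratios scaling kept the size of the difference (median -1.21) and left it just short of the threshold (adjusted p = 0.0508).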

How the results depend on the processing

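The fit without both S1 replicate 1 and S3_S replicate 3, the block within the 6 libraries of S3_S and S3_C and the gene ontology tests were chosen after the values were seen, and the other settings here were fixed earlier. Counts of called genes were unchanged in all 6 comparisons with median-of-ratios scaling, quantile normalization, eBayes without a trend and a minimum change of 2-fold. No list and no gene chosen for the text reversed its direction while called in any setting. Other genes were not checked for this. The GO term photosynthesis in S3_C against S2, not called with all libraries (median -0.07), was called lower without S3_C replicate 1 (-0.36) and higher without S2 replicate 3 (0.13) or S3_C replicate 3 (0.12). Without 1 library in turn, S2 against S1 had 0 to 1278 genes higher, 1 to 2984 lower and 4 to 7 lists, S3_S against S3_C 0 higher in each fit, 0 to 5 lower and 1 to 3 lists, S3_C against S2 0 to 4 higher, 0 lower in each fit and 0 to 3 lists, S3_S against S2 0 to 2 higher, 0 lower in each fit and 0 to 6 lists, S3_C against S1 0 to 1747 higher, 1 to 4540 lower and 0 to 7 lists, and S3_S against S1 0 to 99 higher, 1 to 282 lower and 0 to 5 lists. The highest gene counts against S1 came from the fit without S1 replicate 1. In the fits without 1 library of a group, the remaining 2 were assumed to vary like the other groups.

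With no filter, 1 gene was lower in S2 against S1, 3 lower in S3_S against S3_C, 2 higher in S3_C against S2, 3 higher and 1 lower in S3_C against S1, and 1 lower in S3_S against S1. With a minimum of 5 FPKM, 0 were lower in each of the 3 comparisons against S1. With only the 6 libraries compared, 2 were higher and 0 lower in S2 against S1, 1 higher and 2 lower in S3_S against S3_C, 1 higher in S3_C against S2, 2 higher in S3_S against S2, and 1 higher and 1 lower in both S3_C and S3_S against S1. With the replicate number as a block, 1 gene was lower in each comparison against S1 and 1 list was called in S3_S against S2, and the block changed no other count. With a pseudocount of 0.1, 1 gene was higher and 1 lower in S3_S against S3_C, 3 were lower in S3_C against S1, and 5 lists were called in S2 against S1 and 4 in S3_S against S2.

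Array quality weights, whose fit did not fully converge and gave S1 replicate 1 a weight of 0.19 and S2 replicate 2 a weight of 9.51, called 5970 genes higher and 8831 lower in S2 against S1, 2 and 4 in S3_C against S2, 400 and 377 in S3_S against S2, 3570 and 8725 in S3_C against S1, and 3128 and 4668 in S3_S against S1. Without both S1 replicate 1 and S3_S replicate 3, 1536 genes were higher and 3634 lower in S2 against S1, 1932 and 4920 in S3_C against S1, and 914 and 2165 in S3_S against S1, and 2 lists were called in S3_S against S3_C. The block within 6 libraries called 4 lists there. Median-of-ratios scaling gave 0 lists in S3_S against S3_C and in S3_S against S2, and camera with an estimated correlation and fry gave 0 lists in each of the 5 comparisons with calls. For all of these changes the cause was not tested. Read depth limits low values in a way that cannot be stated, since counts are not given in the sources used here.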

Other observations

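The gene ontology tests, the genes annotated to anthocyanin processes, the tests of explanations and the counts of other splits in this part were chosen after the values were seen, and the limma tests and the cell division list were fixed earlier.

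Among gene ontology terms, ribosome genes had lower values in each later group than in S1. The terms were called with a preset correlation between members. With an estimated correlation 0 of 648 terms passed in any comparison (smallest adjusted p = 0.697), and S1 replicate 1 and S3_S replicate 3 stand apart from their groups. The 403 tested ribosome genes fell in S2 against S1 (median log2 fold change -1.02, 29 above 0, camera adjusted p = 1.51e-20, 0.905 with an estimated correlation), S3_C against S1 (-0.999, 7.69e-12) and S3_S against S1 (-0.44, 8.47e-08), and the last call was lost without S1 replicate 3 (median -0.05, adjusted p = 0.484). In S2 against S1 the ribosome median was -1.62 without S1 replicate 1 and -0.62 without S1 replicate 3, in S3_C against S1 -1.58 and -0.61, and in S3_S against S1 -1.05 without S1 replicate 1 and -0.25 without S1 replicate 2. In S2 against S1, the 67 DNA replication genes fell (median -0.66, 8 above 0, adjusted p = 5.68e-06, 0.905 with an estimated correlation, with medians of -0.995 without S1 replicate 1 and -0.42 without S1 replicate 3), and the 93 photosynthesis genes rose (0.77, 71 above 0, adjusted p = 5.42e-07, 0.905 with an estimated correlation, with medians of 1.27 without S1 replicate 1, 0.46 without S1 replicate 2 and 0.45 without S2 replicate 3).

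In the green margin against the red center, microtubule genes rose (71 genes, median 0.61, 66 above 0, adjusted p = 5.48e-05), as did ribosome biogenesis (45, 0.79, 0.000174), cell wall organization (103, 0.55, 0.00142) and auxin signaling genes (69, 0.53, 0.000208), the 4 at adjusted p = 0.942 with an estimated correlation. Without S3_S replicate 3, which resembles S1 replicates 2 and 3, the medians were 0.44 (adjusted p = 0.00763), 0.66 (0.00375), 0.39 (0.0108) and 0.52 (0.00103). Ribosome genes rose in the margin with all libraries (0.54, 0.00118) and did not pass without S3_S replicate 3 (0.38, 0.1497). Chloroplast thylakoid (72, -0.401, 5.45e-05) and autophagy genes (34, -0.16, 0.000174) fell there, the first not without S3_C replicate 1 (-0.13, 0.188) and by a larger median without S3_C replicate 3 (-0.62), and the second by a larger median without S3_C replicate 1 (-0.34) or S3_S replicate 1 (-0.28) and by a smaller median without S3_C replicate 2 (-0.07, 0.0225). In the center against S2, genes of the tricarboxylic acid cycle rose (52, 0.15, adjusted p = 1.2e-05, and adjusted p = 0.850 with an estimated correlation), a call lost without S2 replicate 1 (median 0.08, 0.143) or S3_C replicate 2 (0.101, 0.0739). Of the 648 terms, 34 rose and 94 fell in S2 against S1, 72 and 39 in S3_S against S3_C, 31 and 3 in S3_C against S2, 87 and 20 in S3_S against S2, 59 and 81 in S3_C against S1, and 28 and 26 in S3_S against S1.

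Some genes annotated to anthocyanin processes were outside the lists. The entry of CIP7, a COP1-interacting protein, annotated to these processes averaged 23.9 ± 5.71 FPKM in the green margin and 9.18 ± 5.58 in the red center. Its libraries had 18.7, 30.05 and 23.04 in the margin and 8.24, 4.12 and 15.2 in the center. It did not pass over all genes (limma adjusted p = 0.476). Another entry with the name CIP7 is not given here. The cytokinin response regulator ARR12 averaged 4.87 ± 2.16 FPKM in S1 and 1.75 ± 0.511 in S2, and the blue light receptor CRY1 54.7 ± 28.02 and 83.1 ± 9.45 (limma adjusted p = 0.403 for each). The elongator gene ELP6 averaged 6.999 ± 2.201 in S1 and 3.41 ± 1.32 in the center, and the auxin response factor ARF10 10.9 ± 6.41 and 18.6 ± 6.15 (limma adjusted p = 0.213 and 0.220). None of them passed. In S1 replicates 1, 2 and 3 CRY1 was at 86.9, 36.3 and 40.9 FPKM and ARF10 at 18.3, 7.05 and 7.36. S1 replicate 1 thus had the later level of both, and its ARR12 (2.45) and ELP6 (4.47) values were the lowest of S1.

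S1 replicate 1 and S3_S replicate 3 stood apart from their groups, the first resembling S2 and the third-stage libraries and the second resembling S1 replicates 2 and 3. Scaling between libraries is argued against as the source of this resemblance for S1 replicate 1. After quantile normalization its highest correlation with another S1 library was 0.766 and with a library of another group 0.94. Before normalization these were 0.761 and 0.941. Correlations of log values respond little to scaling, so the normalization step itself adds little. Exchanged labels of these 2 libraries cannot be told apart from other causes. On axes from S1 to S3_S with an S1 library held out (0.0243 to 0.136), S3_S replicate 3 (0.376 to 0.429) stayed 0.261 or more from it. With an S3_S library held out (0.716 to 0.963), S1 replicate 1 (0.629 to 0.984) lay around it and S3_S replicate 3 at 0.3 to 0.37. Only 2 libraries of each group could be held out, and no S2 or S3_C library was placed on these axes. A position near the S3_S end therefore does not separate S3_S from other later libraries. S1 replicate 1 correlated at 0.911, 0.941 and 0.918 with the S2 libraries and at 0.912, 0.879 and 0.927 with those of S3_C. With S3_S replicates 1 and 2 it correlated at 0.886 and 0.867. More dividing tissue in S1 replicates 2 and 3 and S3_S replicate 3 is a candidate explanation. In the cell division list, on genes not chosen for this pattern, the lowest of these 3 libraries exceeded the highest of the other 9 by 0.983. The gap is not particular to that list. Their lowest value also lay above the highest of the other 9 in the early flavonoid (1.031 and -0.11), general phenylpropanoid (0.684 and 0.154) and vascular lists (0.586 and 0.107). These values thus do not single out dividing tissue. Leaves of differing age or position within a sample could differ in dividing tissue, a possibility that remains untested.

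The genes called against S1, Bo8g082410 and Bo9g120520, were detected in the S1 libraries and listed at 0 elsewhere. Listing at 0 unrelated to the groups may account for them: 51 entries were at 1 FPKM or more in 3 libraries and at 0 in the other 9, only 2 of them in the libraries of 1 group, and 12 of the 220 possible triples of libraries (5.45%) held 2 or more such entries. Among the 15 entries that reach 10 FPKM, 2 triples (0.909%) held 2 or more, so the share depends on the level asked for and the explanation cannot be told apart from a difference in S1. S1 replicates 2 and 3 with S3_S replicate 3 held 5 such entries.

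The 6 libraries of each comparison make 10 splits with the real one included, too few for a share under 0.05. With the real split counted, 3 of 10 called at least as many lists as it did in S2 against S1 and in S3_C against S1. The number was 5 in S3_S against S2 and in S3_S against S1, 6 in S3_S against S3_C and 10 in S3_C against S2. The real split called 2 genes in S2 against S1 (highest other 12) and 6 lists (highest other 8), 0 genes in S3_S against S3_C (highest other 2) and 1 list (highest other 6), 0 genes in S3_C against S2 (highest other 17) and 0 lists (highest other 6), and 0 genes in S3_S against S2 (highest other 1) and 3 lists (highest other 6). It called 2 genes in S3_C against S1 (highest other 2604) and 5 lists (highest other 7), and 2 genes in S3_S against S1 (highest other 3976) and 3 lists (highest other 6). The splits with 2604 and 3976 genes, which set S1 replicate 1 with S3_C replicates 1 and 2, or with S3_S replicates 1 and 2, against the other libraries, point to a structure of the samples that crosses the groups. The 12 and 17 genes in S2 against S1 and S3_C against S2 were the highest among the other splits. They were not set against a value expected without change, so nothing is read from them. In S3_S against S3_C, where equal numbers met the criterion for pairing, the real split (0 genes, 1 list) parts all 3 pairs of equal numbers. The 3 others that do so called 0 or 1 genes and 0 or 5 lists. The remaining 6 part 1 pair and keep 2 together, and called 0 to 2 genes and 0 to 6 lists.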
